A study of Mus musculus with 2 samples.

How the data were processed

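Genomic DNA of 2 mouse pancreatic ductal adenocarcinoma (PDAC) cell lines was measured by exome sequencing, 1 library per line. One line is labelled Trp53R172H/-, carrying a missense allele of the tumour suppressor gene Trp53, and the other Trp53-/-. The series' design text names both isogenic Trp53-/- cells, made with CRISPR-Cas9, and syngenic ones, and the title of this Trp53-/- sample calls it syngenic. Beyond that title the origin of the line is not settled here, so whether the lines differ in origin as well as in Trp53 genotype is open. Per the labels' protocols, DNA was purified with phenol and chloroform, exons were captured with an Agilent SureSelect kit for the mouse exome, and the libraries were read as pairs on an Illumina NovaSeq. BWA, GATK and the mm10 build are named per the submitters' processing notes, and their versions and settings are not given in the sources used here.

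Each deposited file is a list of read alignments with chromosome, start, end, read name, a score and strand. The score column deposited by the authors holds whole numbers from 30 to 60 and was read as the mapping quality of each alignment. The lists hold no bases, so single-base alleles such as R172H were outside what could be measured, and variant calls were not analysed here. The Trp53R172H/- file holds 24790570 alignments of 12987670 templates (sequenced fragments) and the Trp53-/- file 23237278 alignments of 12185866 templates. Mapping quality was 60 for 92.9% and 92.7% of alignments, and only 1 mate was listed for 9.12% and 9.31% of templates. Alignments repeating the chromosome, start, end and strand of another made up 0.545% and 0.501%. The median span of a template was 191 and 190 bases.

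Reads were counted per protein-coding gene over the whole gene body, from the first to the last annotated base, with gene positions taken from a RefSeq gene table of the same assembly as mm10. Counting over exons had been planned, but no exon coordinates or genome sequence were used here, so the gene body took its place. A gene was kept when the mean of the 2 libraries was at least 200 reads, which left 18683 of 21883 genes, with a median of 802 reads in the Trp53R172H/- library and 750 in the Trp53-/- library. The relative depth of a gene is the log2 ratio of its reads, Trp53-/- over Trp53R172H/-, minus the median of that ratio over autosomal genes. Its zero point is therefore the typical autosomal gene, and absolute copy numbers are unknown. The 95% intervals of ratios came from template counts and those of single counts from the exact Poisson distribution. PCR-amplified reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. For a kept gene they reached a median of 0.20 to either side on the log2 scale. Where 1 library had no template, the ratio is given as a lower bound against a floor of 3 templates in that library.

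Windows of 1 Mb took the median of their 20 kb bins with a mean of at least 50 reads. Runs of windows were split by circular recursive segmentation, with at least 5 windows per segment and a shift of at least 0.3. Templates lying more than 1 kb from any base with a pooled depth of 20 were counted as off-target. They made up 10.3% of alignments in the Trp53R172H/- library and 10.7% in the Trp53-/- library, and give a second depth profile that depends little on the probes. Off-target log2 ratios were shifted by a common constant, so that over autosomes their median difference from the gene medians vanished. Off-target density was expressed relative to the autosomal median of the same line. No normal diploid library was used here, so bias within a line remains in those densities.

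With 1 library per line there are no replicates, and no p-values or counts of significant genes are given. Genes were described by a fixed size, a log2 ratio of at least 0.4 from 0. The named genes were fixed by rule before the data were examined: Trp53, Kras and Cxcl1, up to 4 members per gene list past 0.4 with the largest ratios first, and the 10 highest and 10 lowest genes with at least 200 reads, at most 2 per 5 Mb. The 10 gene lists were also fixed then, and the median of each list with kept genes was ranked among 10000 random lists of the same size matched on depth. The Y-linked list had no kept gene and was not ranked. The alternatives were scaling by total depth or by the mode of the gene ratios, other filters and thresholds, mapping quality, repeated positions, covered bases, templates in place of reads, window sizes and unmatched random lists. Simulated counts for 17975 genes tested the calculation for this comparison. A log2 ratio of at least 0.4 from 0 was reached by 100% of genes set to 0.5-fold, 54% at 0.75-fold, 100% at 1.5-fold, 100% at 2-fold and 0.428% of unchanged genes. Planted segments of 20 windows with a shift of 0.5 were found in 100 of 100 simulated series, and 100 of 100 flat series stayed whole. Shorter segments and smaller shifts were not simulated, so their recovery is unknown. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, pyarrow 21.0.0 and matplotlib 3.10.9 were used.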

Results

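Exome sequencing was performed on 2 PDAC cell lines of a mouse study of mutant p53, the protein made by Trp53. The Trp53R172H/- line keeps 1 missense allele, and the Trp53-/- line is labelled as having none. Each line contributed 1 library, of 24790570 alignments for Trp53R172H/- and 23237278 for Trp53-/-. Covered bases, 64.9 Mb in all, held 81.4% and 81.2% of these alignments. No replicates exist, so every difference below is between these 2 libraries, and the effect of the Trp53 genotype is not separated from other differences between the lines. Log2 ratios give relative depth in Trp53-/- over Trp53R172H/-, with 95% counting intervals in parentheses, and positions are in mm10.

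Trp53 was examined first, because its state defines the lines. The Trp53-/- library lacked most of the gene. On chromosome 11, no alignment of that library fell between 69582912 and 69591053, a stretch of 8.14 kb inside the gene body (69580348 to 69591873). The ends of this stretch were set by the nearest reads of the Trp53-/- library, so its count of 0 is given by that choice. The Trp53R172H/- library had 262 templates there (exact Poisson interval 231 to 296). Of 10 blocks of the gene, set by a pooled depth of at least 10, 9 had no read in the Trp53-/- library. These 9 all lie inside the empty stretch, so they restate it and add no separate evidence. The shortest of them span only 6, 8 and 13 bases. The remaining block, at 69591058 to 69591526 toward the 3′ end, had a mean depth of 28.8 in Trp53R172H/- and 28.9 in Trp53-/-. Over the part of the gene 3′ of the empty stretch, 69 and 68 templates gave a log2 ratio of 0.10 (-0.38 to 0.58). The part 5′ of it held only 5 and 3 templates. Over the whole gene, 639 reads in Trp53R172H/- stood against 136 in Trp53-/-, a log2 ratio of -2.11 (-2.48 to -1.74). Exon boundaries were not used here.

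**Figure D1:**
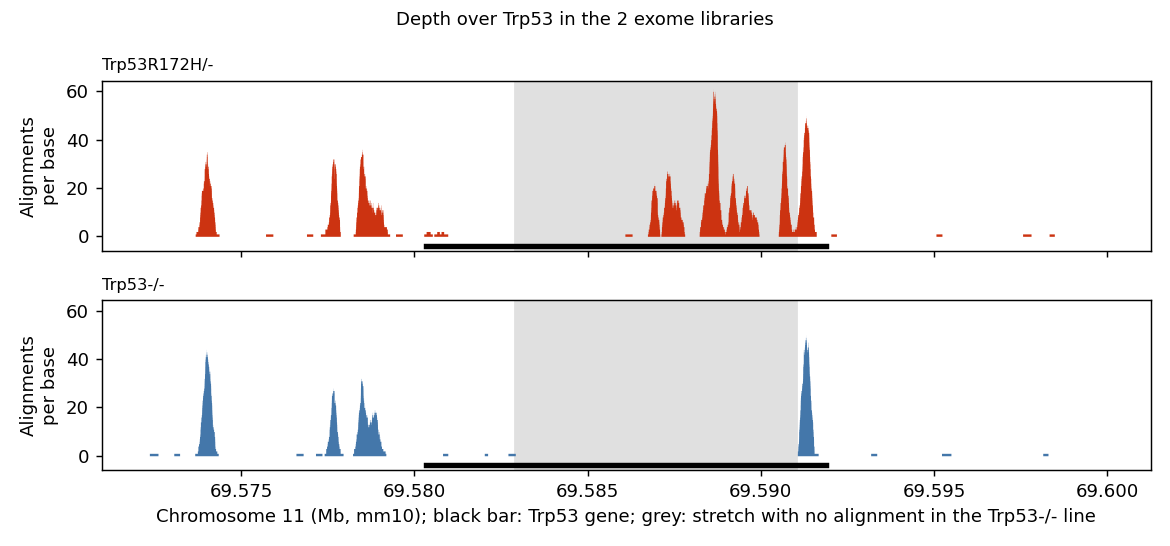
Depth over Trp53 in the Trp53R172H/- library (top) and the Trp53-/- library (bottom), with position on chromosome 11 in Mb on the horizontal axis and alignments per base on the vertical axis. The black bar is the gene and the grey band the 8.14 kb without an alignment in the Trp53-/- library, where the Trp53R172H/- library has 262 templates.

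The 82 genes within 1 Mb of Trp53 had a median log2 ratio of 0.16 (quartiles -0.13 and 0.41). Between 69.3 and 70 Mb, 43 genes had a median log2 ratio of 0.40, and the 20 kb bins had a median of 0.39. The bins on either side had medians of -0.11 (66 to 69.24 Mb) and -0.21 (70 to 73 Mb). Polr2a, which encodes the largest subunit of RNA polymerase II, was at 0.40 (0.29 to 0.52), Kdm6b, a histone demethylase gene, at 0.39 (0.22 to 0.56) and Chd3, a chromatin remodeller gene, at 0.42 (0.30 to 0.53). Off-target templates in this stretch gave 0.28 (0.05 to 0.52). The stretch and these neighbours were chosen after their values were seen.

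The other genes at the centre of the study showed smaller differences. Kras, the driver oncogene of these tumours, had 553 and 402 reads and a log2 ratio of -0.34 (-0.59 to -0.08), near the median of -0.45 of the 10 genes around it on chromosome 6. Cxcl1, the neutrophil-attracting chemokine named in the study's title, had 269 and 240 reads and a ratio of -0.04 (-0.39 to 0.30), so no difference was detectable at this depth.

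Relative depth across the genome was compared to see how far the lines differed outside Trp53. Whole chromosomes and large parts of chromosomes differed. Chromosome 10 was higher in Trp53-/-, with a median log2 ratio of 0.58 over 856 genes, or 1.5-fold. Chromosome 12 had a median of 0.48 over 577 genes, but in parts: windows from 38 to 62 Mb and from 67 to 116 Mb were at 0.54 and 0.52, while those from 3 to 38 Mb were at 0.12, 62 to 67 Mb at 0.04 and 116 to 121 Mb at 0.12. Chromosome 6 was lower in Trp53-/-, with a median of -0.42 over 999 genes, and chromosome 8 had -0.32 over 907. Chromosome 13 had 0.36 and the X chromosome 0.28. On chromosome 7 the difference lay in the first part: windows from 3 to 35 Mb had a median of 0.57 and those from 35 to 146 Mb 0.05. Chromosomes 1 and 2 had medians of 0.01 and -0.01, and that of chromosome 1 turned to -0.02 under scaling by total depth. Medians were at least 0.4 from 0 on 3 of the 20 chromosomes compared, while the typical SD of genes within a chromosome was 0.16. Off-target ratios had been shifted by a common constant to centre them on the autosomal gene medians. After that shift they lay within 0.07 of the gene medians, with the same sign on 19 of 20.

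**Figure D2:**
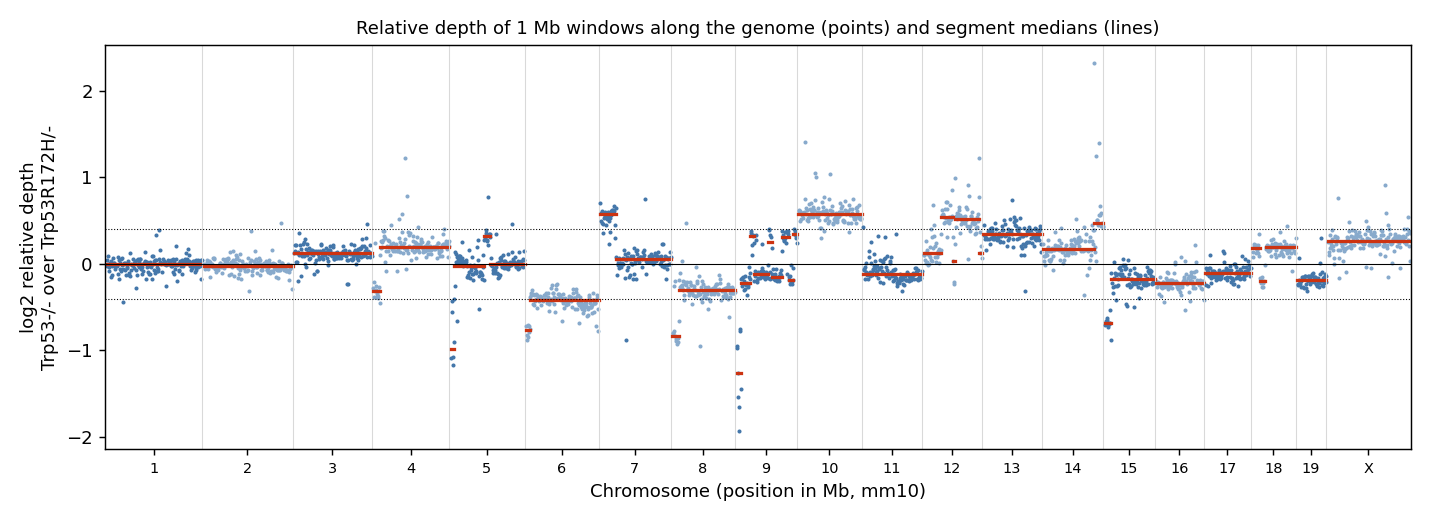
Log2 relative depth, Trp53-/- over Trp53R172H/-, of 2526 windows of 1 Mb (points) along chromosomes 1 to 19 and X, with medians of the 43 segments as lines and dotted lines at 0.4 from 0. Chromosome 10 lies at 0.58 along its length, chromosome 6 mostly at -0.41, and the start of chromosome 9 at -1.26.

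In all, 2346 of the 18683 kept genes (12.6%) had a log2 ratio of 0.4 or more, 1141 (6.11%) had -0.4 or less, and 15196 (81.3%) lay between. The genes past this size clustered by chromosome. Chromosomes 7, 10, 12 and 13 held 81.3% of the higher genes, with 502, 789, 375 and 242 of them, and chromosomes 6 and 8 held 70.4% of the lower genes, with 564 and 239. Segmentation divided the genome into 43 segments and left 10 chromosomes whole. Of the segments, 5 had a median of 0.4 or more and 6 had -0.4 or less. The lower ones included the first parts of chromosomes 8 (3 to 16 Mb, -0.84), 6 (3 to 11 Mb, -0.77) and 15 (3 to 15 Mb, -0.69). The counts of genes depend on the size and the read minimum chosen: 4087 and 2896 genes passed 0.25, and 802 and 367 passed 0.4 with at least 1000 reads.

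Among the segments of 1 Mb windows, the window medians farthest from 0 were those at the starts of chromosomes 9 and 5, where depth was higher in the Trp53R172H/- library. The segment of chromosome 9 from 3 to 12 Mb had a median of -1.26, and off-target templates there gave -1.24. Within it lie Yap1, the transcriptional coactivator of the Hippo pathway, at -2.27 (-2.43 to -2.11), and the inhibitor of apoptosis genes Birc2, at -2.19 (-2.32 to -2.05), and Birc3, at -2.12 (-2.24 to -2.0). Yap1 had 3726 reads in Trp53R172H/- and 709 in Trp53-/-, 4.83-fold more after scaling. Mmp20, a matrix metalloproteinase gene next to them, was at -2.32 (-2.46 to -2.18). The segment of chromosome 5 from 3 to 9 Mb had a median of -0.98 over 6 windows, while its 35 kept genes had a median of -0.63. It holds Cdk6, a G1 cyclin-dependent kinase gene, at -2.14 (-2.28 to -2.0) with 4569 and 950 reads, and Rbm48 at -2.01 (-2.16 to -1.86). Sri, a calcium-binding protein gene, was at -1.31 (-1.46 to -1.16) and Adam22 at -1.27 (-1.34 to -1.19).

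At a finer scale, chosen after these segments were seen, the bins of both loci lay in steps. On chromosome 9 the 720 kb from 7.62 to 8.34 Mb, with 8 kept genes, had a median of -2.24, or 4.72-fold more in Trp53R172H/-. The 4.42 to 7.6 Mb before it had -1.33. On chromosome 5 the bins from 3.2 to 3.36 Mb had -2.35 and those from 3.36 to 3.62 Mb -1.99, and 6.42 to 8.62 Mb had -1.19. A step at 3.36 Mb is not established, because the quartiles on either side overlapped (-2.53 to -2.09 and -2.22 to -1.92). The off-target intervals there overlapped too (-2.79 to -2.14 and -2.44 to -1.94). Off-target density within the Trp53R172H/- line was 4.28 times its autosomal median in the chromosome 9 core (4.07 to 4.49), and 0.79 times in Trp53-/- (0.70 to 0.89). In the chromosome 5 stretches from 3.2 to 3.36 Mb and from 3.36 to 3.62 Mb it was 5.23 and 5.98 times in Trp53R172H/-, and 0.97 and 1.35 times in Trp53-/-. Outside these cores both lines departed from their medians. Chromosome 9 from 4.42 to 7.6 Mb was at 1.31 times in Trp53R172H/- and 0.53 times in Trp53-/-. Chromosome 5 from 6.42 to 8.62 Mb was at 1.37 and 0.65 times.

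**Figure D3:**
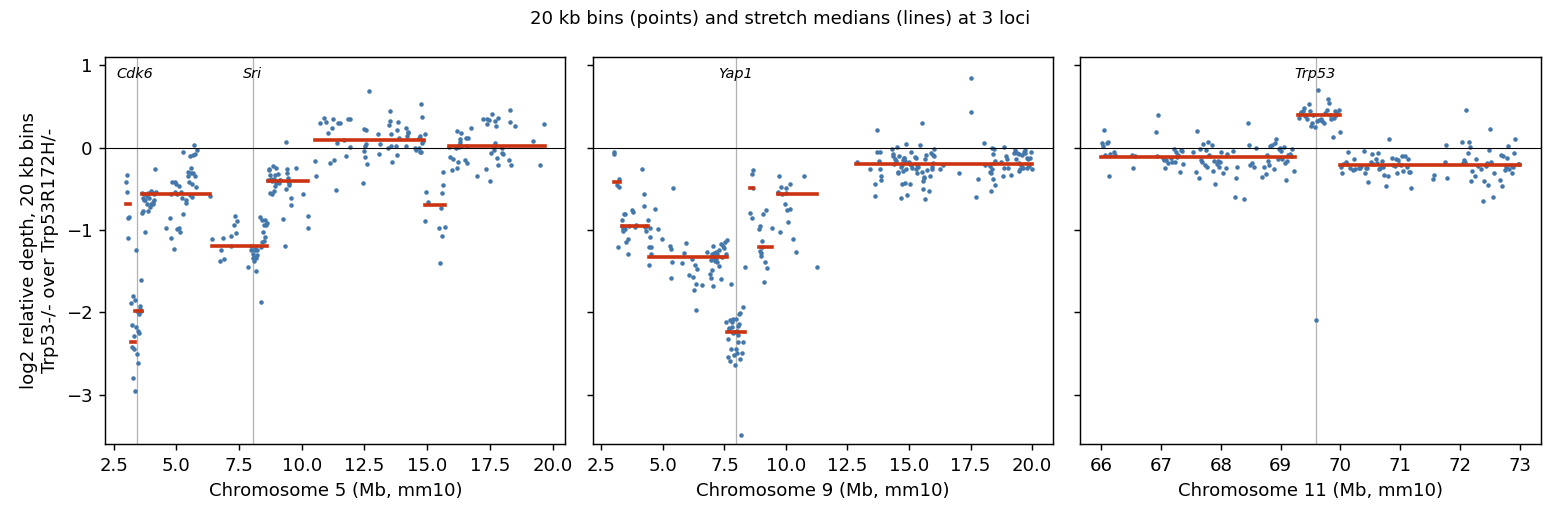
Log2 relative depth, Trp53-/- over Trp53R172H/-, of 20 kb bins (points) with stretch medians (lines) on chromosomes 5, 9 and 11, position in Mb. The bins around Cdk6 reach -2.35 and those around Yap1 -2.24, and the bins from 69.3 to 70 Mb on chromosome 11 lie at 0.39 apart from the bin that holds Trp53.

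Gene lists fixed before the data were examined were compared next. Members named beyond the rule were chosen after their values were seen. Of 25 kept oncogenes known to be amplified in tumours, 5 were at -0.4 or less: Cdk6, Yap1, Birc2, Birc3 and Met, the hepatocyte growth factor receptor gene on chromosome 6, at -0.41. Of them 3 were at 0.4 or more: Akt2 on chromosome 7 at 0.83 (0.67 to 0.99), Mdm2 at 0.49 and Cdk4 at 0.43, both on chromosome 10. Myc was at -0.37 (-0.67 to -0.06). The list median of -0.03 ranked at percentile 24.5 of random lists. Of 21 kept tumour suppressor genes of pancreatic cancer, Trp53 was lower and Stk11, a kinase gene on chromosome 10, higher at 0.71 (0.48 to 0.93), with its neighbours at 0.51. The other 19 lay between, including Smad4 at 0.17 (-0.01 to 0.35) and Pten at -0.19 (-0.33 to -0.04), and the median of 0.08 ranked at percentile 87.3. Cdkn2a and Cdkn2b were below the read minimum, with 124 and 140 reads for Cdkn2a and 32 and 22 for Cdkn2b, whose ratio of -0.42 had a wide interval (-1.53 to 0.69). Both genes had reads in both lines. The 4 kept genes of the Cdkn2a neighbourhood had a median of 0.21 (percentile 82.9), with Ifna1 at 0.86 (0.55 to 1.17) and its neighbours at 0.21. All 4 lie together on chromosome 4, in a segment at 0.20. Random lists were not matched for such linkage, so this percentile reflects the level of a single locus.

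Of 13 kept p53 target genes, 5 were at 0.4 or more and 2 at -0.4 or less. The higher ones were Tnfrsf10b, a death receptor gene, at 0.66 (0.40 to 0.92), Sesn1 at 0.66 (0.51 to 0.80), the DNA polymerase gene Polk at 0.57 (0.43 to 0.70), Mdm2 and Aen at 0.42. Perp, below the read minimum, was at 0.67 (0.26 to 1.09). Sesn1 and Perp, like Mdm2, lie on chromosome 10, and the genes around them had medians of 0.59 and 0.60. The genes around Polk on chromosome 13 had 0.41 and those around Tnfrsf10b on chromosome 14 had 0.26. The lower ones were Trp53inp1 at -0.56, in a chromosome 4 segment at -0.31, and Tigar at -0.47, in a chromosome 6 segment at -0.41. The list median was 0.06 (percentile 66.4). Within the p53 family of 3 genes, Trp63 was at -0.23 and Trp73 at 0.21, with a median of -0.23 (percentile 8.70). Of 15 DNA repair genes, the checkpoint kinase genes Chek1 and Atr, both on chromosome 9, were at 0.46 (0.24 to 0.68) and 0.42 (0.33 to 0.50), with neighbours at 0.36 and 0.31. The other 13 lay between, with a list median of 0.07 (percentile 83.0).

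Of 12 kept Cxcl chemokine and receptor genes, none reached 0.4 and 2 were at -0.4 or less: Cxcl12 on chromosome 6 at -0.64 (-1.04 to -0.25), with neighbours at -0.46, and Pf4 on chromosome 5 at -0.61 (-0.96 to -0.26). Their median of -0.21 ranked at percentile 0.85. Among 19 antigen presentation and interferon pathway genes, Ifngr1, the interferon gamma receptor gene on chromosome 10, was at 0.63 (0.44 to 0.83), with neighbours at 0.55, and the immunoproteasome gene Psmb9 at -0.52 (-0.83 to -0.22). The other 17 lay between, among them B2m at -0.07, and the list median of -0.16 ranked at percentile 1.24. Many members of both lists lie near each other on chromosomes 5 and 17, and the random lists were not matched for such linkage. Pf4 and Psmb9 were lower than the genes around them, whose medians were -0.06 and -0.13. All 10 kept pancreas identity genes lay between, with a median of 0.02 that turned to -0.01 under scaling by total depth (percentile 50.2). Ptf1a, an acinar transcription factor gene below the read minimum, was at -0.96 (-1.57 to -0.35) with 127 and 60 reads.

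Sex chromosomes were compared within each line. The first 3 Mb of chromosome Y had 1102 templates in Trp53R172H/- and 0 in Trp53-/-, at least 338-fold more. All 9 listed Y-linked genes had reads in Trp53R172H/- and none in Trp53-/-, among them Usp9y with 355 reads, Kdm5d with 313, Uty with 206 and Uba1y with 182. For these the depth was at least 55.8-fold, 50.6-fold, 32.5-fold and 29.1-fold higher. All templates in the first 3 Mb of chromosome Y, captured ones included, were set against the autosomal off-target median of the line. Their density was 0.565 (0.532 to 0.599) of it in Trp53R172H/- and under the floor of 0.00167 in Trp53-/-. This measure therefore differs from the off-target density of the X chromosome that follows. Off-target density of the X chromosome was 0.39 and 0.51 times the autosomal median. Among autosomes, chromosome 10 was at 0.66 in Trp53R172H/- and 1.05 in Trp53-/-, chromosome 6 at 0.98 and 0.74, and chromosome 8 at 1.26 and 1.0.

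**Figure D4:**
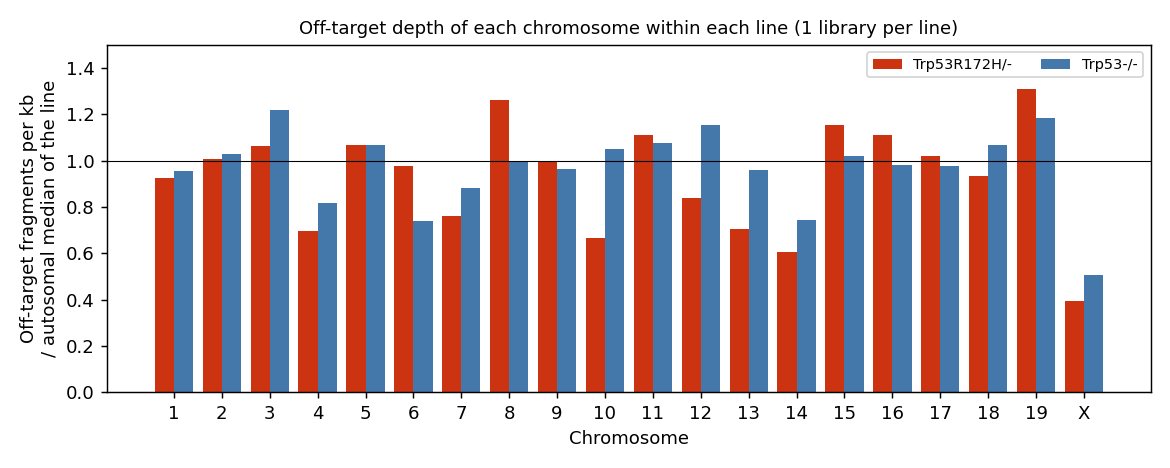
Off-target templates per kb of each chromosome divided by the autosomal median of the same line, for Trp53R172H/- (red) and Trp53-/- (blue), 1 library per line. Chromosome 10 stands at 0.66 and 1.05, chromosome 6 at 0.98 and 0.74, and the X chromosome at 0.39 and 0.51.

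Most of the remaining genes at the ends of the range stood apart from their neighbours, and several belong to multigene families. Cyp2a22, a cytochrome P450 gene on chromosome 7, had 1500 reads in Trp53-/- and 0 in Trp53R172H/-, at least 283-fold more, and it was the 1 kept gene without a read in a line. Cwc22, a splicing factor gene on chromosome 2, was at 2.42 (2.34 to 2.5) with 2622 and 12900 reads, while the median of its neighbours was 0.03. Slfn8, a Schlafen family gene on chromosome 11, was at -2.40 (-2.62 to -2.19) against -0.23 for its neighbours. The other highest genes were Olfr331 at 2.72, Ifnz at 1.66, Serpina1e at 1.65, Olfr320 at 1.61, Gm2046 at 1.58, Gm6803 at 1.49, Pira2 at 1.42 and Gm9595 at 1.38. Gm21190 at -1.37 and Gm3727 at -1.30 were among the lowest. The neighbours of Gm21190 were lower too, at -0.53. Off-target templates of its stretch on chromosome 5, from 14.9 to 15.72 Mb, gave -1.26 (-1.55 to -0.98). In Gm2046 75% of the Trp53R172H/- alignments had a mapping quality below 60, against a median of 4.97% over kept genes. Values of such family members are uncertain, because near-identical copies can share reads.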

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

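Alignments outside the compared chromosomes drew attention because they exceeded what a count of 0 allows, with no control library to set them against, and they were counted after the files had been seen. The mitochondrial genome held 34817 alignments in Trp53R172H/- and 38822 in Trp53-/-, or 0.140% and 0.167% of each library. Unplaced or unlocalised contigs held 56476 alignments in Trp53R172H/- and 50768 in Trp53-/-. On chromosome Y from 90 Mb on, 22 templates lay in Trp53R172H/- and 75 in Trp53-/-, the reverse of the order over the first 3 Mb of that chromosome. These 75 were all the templates of Trp53-/- on chromosome Y, and the rest of the chromosome held none. Whether they came from chromosome Y itself was not tested, so they do not show that the Trp53-/- line holds part of it.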

How the results depend on the processing

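Mapping quality 60 only, covered bases only, templates in place of reads, and summed windows were chosen after seeing the data, and scaling by total depth, planned for genes in general, was added then for the Trp53 locus. No result reversed among the called values, and of 258 alternatives for named genes 253 stayed within the counting interval. That count includes mapping quality 30 or more and scaling by total depth or by the mode. These shift every gene alike, by less than the intervals allow, so they could not have moved any gene. Counts of genes followed the threshold and filter, as the construction of those alternatives gives: at or above the threshold there were 4087 genes at 0.25, 866 at 0.6 and 802 with at least 1000 reads, against 2346, and at or below its negative 2896, 348 and 367, against 1141. Windows of 5 Mb gave 25 segments and windows of 250 kb gave 79, against 43. A segment needs at least 5 windows at every size, so the shortest possible segment grows with the window. The counts therefore depend on the window by construction, and whether anything else adds to this was not tested. The Trp53 ratio of -2.11 was -2.0 when scaled to the other genes of chromosome 11. It was -1.54 on covered bases only, which leave out part of the emptied stretch because its pooled depth is low. With mapping quality 60 only, Olfr331 moved to 3.30, Olfr320 to 2.14, Gm2046 to 2.0 and Slfn8 to -2.62. These shifts follow from unequal shares of alignments below 60 in Trp53R172H/- and Trp53-/-. The shares were 47.1% and 21.3% for Olfr331, 45.6% and 21.4% for Olfr320, 75% and 66.8% for Gm2046, and 5.98% and 19.2% for Slfn8. Why the shares differed was not tested. Scaling by total depth moved the median autosomal gene by -0.03. Keeping mapping quality 30 or more changed nothing, because every alignment already has it. The planned correction for GC content and the planned threshold on variant calls were not run, and counting over exons was replaced by gene bodies. No paired analysis was possible because each line has 1 library. Depth limits single genes to differences larger than about 0.20 on the log2 scale at the median gene.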

Other observations

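The test of capture efficiency between chromosomes was written after its result was seen, the test of gene density around Trp53 was set after a first look at such contrasts elsewhere, and the stretch around Trp53 was chosen after the genes were seen. Smaller segments alternated along chromosome 9. Medians were 0.32 from 31 to 38 Mb, where Chek1 lies, -0.12 from 38 to 67 Mb, 0.25 from 67 to 75 Mb, -0.15 from 75 to 94 Mb, 0.32 from 94 to 108 Mb, where Atr lies, -0.19 from 108 to 118 Mb and 0.34 from 118 to 125 Mb. Off-target templates gave 0.36, -0.08, 0.20, -0.12, 0.25, -0.15 and 0.39 in the same order. On chromosome 18 the segment from 19 to 29 Mb was at -0.20, between segments at 0.18 and 0.20, and the first 3 to 17 Mb of chromosome 4 were at -0.31 against 0.20 for the rest. Whether the Trp53-/- line came from a female animal or lost chromosome Y was not tested.

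The first pattern weighed is the difference in median between chromosomes. Capture efficiency is argued against by off-target ratios, which followed the gene ratios over 19 autosomes with a slope of 1.04, and lower mapping quality by chromosome medians that moved by at most 0.00559 with mapping quality 60 only. Removing a trend of 1 Mb windows with their captured reads, which stood in for gene density, left 0.963 of the SD of chromosome medians. A bias with GC content was not tested. A difference in chromosome copies between the lines is a hypothesis that remains, and neither the Trp53 genotype nor a separate origin of the lines was tested as its cause.

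The second pattern is the higher depth of Trp53R172H/- around Yap1, Birc2 and Birc3 and around Cdk6. Reads shared between gene family members are argued against by off-target templates of the chromosome 9 segment, at -1.24 ± 0.06 (95% counting interval). Capture efficiency is argued against by off-target templates of Cdk6 with 100 kb on both sides, at -2.28 ± 0.21 from 1121 and 218 templates. Extra copies in the Trp53R172H/- line may account for the pattern in the narrow stretches around Yap1 and Cdk6. Over the whole chromosome 9 segment, off-target density was 1.34 times the autosomal median in Trp53R172H/- and 0.58 times in Trp53-/-. Over the chromosome 5 segment it was 1.67 and 0.82 times. Density there was thus also below the median in Trp53-/-, and no diploid library was used to say which line differs. A cause in the Trp53 genotype was not tested.

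The third pattern is the contrast between the genes around Trp53 and those farther out on chromosome 11. Gene density, measured as the number of 20 kb bins with enough reads, is argued against as the whole cause: around 2334 genes in stretches as dense elsewhere the contrast had a median of -0.00984 (quartiles -0.04 and 0.02), against 0.58 here. Capture efficiency stays open: the off-target contrast was 0.46 (0.20 to 0.72), above 0, but its lower end of 0.198 missed the bound of 0.2 set beforehand. Off-target density of the stretch was 1.26 in Trp53R172H/-, near the 1.25 and 1.29 beside it, and 1.58 in Trp53-/-, above 1.20 and 1.12, without a diploid library to say which line differs. Fewer copies around Trp53 in Trp53R172H/- or more in Trp53-/- could both give the contrast.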
